A study of Mus musculus with 8 samples.

How the data were processed

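The series profiled small RNA at each step of chromatoid body purification from adult mouse testis. The chromatoid body is a cytoplasmic ribonucleoprotein granule of round spermatids, the haploid cells that follow meiosis. Per the labels' protocols, cells of the seminiferous tubules were cross-linked with formaldehyde, sonicated in RIPA buffer and spun into a supernatant and a first pellet. The first pellet was sonicated and filtered, and a second pellet was used for immunoprecipitation (IP) with an antibody to MVH, the mouse vasa homolog DDX4, or to ACR, the acrosomal protease acrosin, as control. RNA of 19 to 33 nt was selected on a gel before libraries were made. The 8 samples fell into 7 groups: lysate, supernatant, first pellet, second pellet, ACR IP and sorted round spermatids with 1 library each, and MVH IP with 2 libraries. The round spermatids carry the label hetMIWI; MIWI is the mouse PIWI protein PIWIL1, and the labels say nothing more of the genotype. All mice were C57BL/6 of at least 6 weeks.

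The submitters' processing notes name TopHat, Cuffdiff and the mm9 build for the authors' files, with no roles or versions; these, the annotation and the treatment of reads with several matches were not given in the sources used here. The authors' 5 tables hold FPKM, a fragment count scaled to feature length and library size. The unit is named per the file headers for the round spermatids; for the other tables it was taken from Cuffdiff's column names, the processing notes and the values. The supernatant, pellet and ACR IP tables each have a fraction column and a lysate column. The supernatant and pellet tables also hold the authors' deposited p-values, q-values, test statistics, which are a score with no fixed range, and calls. The labels tie the pellet column to both pellet samples without saying which it holds, so it is reported as the authors' pellet value with no n. The MVH IP table has 1 small RNA column for both libraries; whether it pools, averages or picks them is not given in the sources used here, and it is reported as the authors' value. A further column of that table, with long RNA values, belongs to no sample here, and this 1 column was not used. The tables list piRNA clusters by number, microRNA genes, small structured RNA genes (small nucleolar, small nuclear and related RNA), other named genes and transcripts assembled without annotation, whose names begin with Cuff. Repeat families were not among the listed features.

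All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. With 1 column of values per group no test between groups was possible, and differences have no replicate check: they compare libraries, not conditions. For each fraction and lysate pair, the log2 ratio of (fraction FPKM + 1) to (lysate FPKM + 1) was taken within the table, for features at or above 1 FPKM in either column. Features at least 2-fold higher or lower were counted. Fold changes on this scale understate the change of low features. Transcripts of the MVH IP table with the same symbol and locus were summed. For 21 gene lists and for piRNA clusters, the median log2 ratio was given with its percentile among 10000 random lists of the same size matched on mean expression in 10 bins (seed 1), when at least 3 members were measured. No percentile was computed for the classes of other named genes and assembled transcripts. The lists, the main settings and the rule for named features were written before the data were examined. The classes of piRNA clusters and of assembled transcripts were defined after the files were opened. The rule took the 12 highest and 12 lowest log2 ratios per comparison, up to 4 members per list with the largest absolute ratio, and for the tables of levels the 20 highest features and the 3 highest of each list. Levels in the MVH IP and round spermatid tables were ranked within the table, and list percentiles there were not matched on expression, since the level is the expression itself. Values set across tables come from separately normalized columns.

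Depth was examined through the values themselves. Among low features, the ratio of fraction to lysate clustered on exact multiples of a step. In the supernatant table, 510 features lay on multiples of 0.667 by ratios of whole numbers up to 6, within a log tolerance of 2e-05, against 4 for a step moved by 1%. A supernatant read was thus worth 0.667 of a lysate read. An ACR IP read was taken as worth 20.0 lysate reads (244 features against 0). The ratio shared by the most features was 10 (43 features, against 34 at 20). Whole-number multiples cannot tell a step of 10 from 20. That library is shallow with either step. ACR IP read numbers and simulated ACR IP reads below use 20, and would be larger with 10. The pellet table showed steps of 0.308 (66 features against 0) and 0.412 (33 against 0). From the authors' test statistic the counting SE of each log2 ratio was derived as the authors' log2 ratio, which has no pseudocount, divided by the statistic. The implied lysate reads had a median of 9980 per piRNA cluster, 77.1 per microRNA gene, 26.8 per other named gene, 7.46 per small structured RNA gene and 3.25 per assembled transcript. piRNA clusters held 90.7% of those reads and 0.465% of the lysate FPKM sum, and microRNA genes 3.79% and 98.1%, because FPKM divides by feature length. These SEs cover counting error only. Total reads per library were not given in the sources used here.

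The lysate column is the same library throughout. Its values in the supernatant table were 0.418 times those in the pellet table for all 1708 features compared, within 1%. Between the ACR IP and pellet tables the median ratio was 0.867, with 60.3% of 1751 features within 1% of it and 110 below 0.5 times it, so the lysate values of that table are not a constant multiple of the others.

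The procedure was tested on simulated reads at each table's depth with 4-fold changes planted. In the supernatant setting (4151 features) 99% of planted increases and 67.9% of planted decreases passed 2-fold, against 3.98% of unchanged features. In the pellet setting (4120 features) these shares were 89%, 69.2% and 7.15%, and in the ACR IP setting (4159 features) 84.8%, 76.2% and 14.3%. The simulation used features of the supernatant table, and its ratios were scaled to the lysate and centred. The scale came from features above 0 in both columns, although 1050 of 2543 ACR IP values were 0. The shares therefore do not describe the uncentred pellet and ACR IP counts given below. No unchanged feature with at least 100 lysate reads passed in any setting. A common scale factor is compressed by the pseudocount at low values: a log2 factor of -2.71 in the pellet column came out as -1.81 for features under 10 FPKM in the lysate and -2.70 at or above 100 FPKM. The alternatives tried were pseudocounts of 0.1 and 10, no filter, a minimum of 10 FPKM, centring on the median, loci of at least 200 bp, leaving out microRNA and small structured RNA genes, a 4-fold threshold, Pearson in place of Spearman correlation, and lists not matched on expression. A listed locus can span the host gene: of 165 microRNA genes of the pellet table at loci of at least 200 bp, 152 had a reference transcript (GENCODE M21), all under 200 nt, so that setting does not leave out short genes.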

Results

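Small RNA of 19 to 33 nt was measured in 8 libraries that follow chromatoid body purification from adult C57BL/6 testis: lysate, supernatant, 2 successive pellets, MVH IP (2 libraries, given as 1 column), the ACR IP control, and sorted round spermatids. The tables held 5096 features for supernatant and lysate, 3005 for pellet and lysate, 2543 for ACR IP and lysate, 8959 for MVH IP and 1014 for round spermatids. Coordinates are mm9. Every group other than MVH IP had 1 library, so no difference below has a replicate check, and SEs are those implied by the authors' test statistic for ratios without a pseudocount. microRNA genes held 98.1% of the lysate FPKM sum in the supernatant table, and the germ cell microRNA Mir34c (chromosome 9, 50911138 to 50911215) alone 19.2%. By reads the order was the opposite, with 90.7% of implied lysate reads in piRNA clusters, the loci that give rise to PIWI-interacting RNA.

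The first comparison asked which small RNAs stayed in solution when the lysate was spun. The supernatant resembled the lysate, and the largest list medians were those of microRNA families. Of 387 microRNA genes, 61 were at least 2-fold higher and 49 at least 2-fold lower, with a median log2 ratio of 0.21 (100th percentile of matched random lists). The Mir34 and Mir449 family, which is abundant in meiotic and haploid germ cells, had a median of 0.67 over 6 genes (percentile 99.3). Mir449a was at 975179 FPKM against 434923 in the lysate, a log2 ratio of 1.16 (SE 0.017), Mir34b had 0.76 (SE 0.018) and Mir34a 1 (SE 0.033), whereas the rarer Mir449b had -1.58 (SE 0.92). The let-7 family had a median of 0.49 over 11 genes (percentile 99.0), led by Mirlet7f-2 with 0.83 (SE 0.043). Genes of the X-linked testis microRNA cluster had 0.44 over 17 genes (percentile 99.5), led by Mir471 with 1.49 (SE 0.090) and Mir465 with 1.19 (SE 0.070).

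Members of the miR-17-92 group and its paralogs did not move together: the list median was 0.15 over 14 genes (percentile 87.9). Mir19a was lower in the supernatant, with a log2 ratio of -1.02 (SE 0.070), as were Mir19b-1 with -0.97 (SE 0.050) and Mir19b-2 with -0.96 (SE 0.050), which share a mature sequence and whose reads can be shared. Mir25 was higher, with 0.96 (SE 0.060). The somatic microRNAs had a median of -0.07 over 9 genes (percentile 30.6). Within that list the red cell microRNA Mir451 had 0.91 (SE 0.028) and the smooth muscle microRNA Mir145 had -0.87 (SE 0.13). In the authors' deposited table, 42 microRNA genes were called higher and 7 lower in the supernatant; at a q-value below 0.05 in the authors' deposited table there were 96 and 36.

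piRNA clusters lay close to the lysate in the supernatant. Their median log2 ratio was -0.07 over 181 clusters, with 129 below 0 and 52 above. The percentile was 2.9, inside the central 95%; it was 0.1 among lists not matched on expression and 31 on loci of at least 200 bp. The authors' deposited table called 60 clusters lower and 5 higher (94 and 18 at a q-value below 0.05), and the median implied SE was 0.019. Small RNA on other named genes lay close to the lysate; whether it is fragments of mRNA, piRNA or repeat reads was not tested. Among 3531 such genes, 40 were higher and 33 lower, with a median of 0.02. Genes of late spermatid chromatin and the sperm tail had 0.26 over 22 genes (percentile 99.7), with Oaz3 at 0.57 (SE 0.18) and Odf1 at 0.47 (SE 0.16). Tssk3 of that list had -0.38 (SE 0.42). Ribosomal protein genes had 0.18 over 72 genes (percentile 100), with 3 at least 2-fold higher and 1 lower. Rps25 was at 1.20 (SE 0.54). Rps27, listed at 0 in the supernatant, had -3.50, and Rpl26, listed at 0 in the lysate, had 3.04. The other lists lay inside the range of random lists. These were chromatoid body and piRNA pathway proteins with 0.05 over 17 genes (percentile 66.0), acrosome proteins with 0.02 over 11 (52.6), spermatocyte genes with 0.19 over 13 (94.1), Leydig cell genes with 0.21 over 3 (81.2), nuclear long non-coding RNA with 0.32 over 4 (86.0), house-keeping genes with 0.06 over 8 (67.8), histone genes with 0.05 over 61 (80.4), loci without a functional name with 0.03 over 565 (65.7) and small structured RNA with -0.08 over 102 (4.6). The small structured RNA list lay outside that range without matching on expression (0.8) and on loci of at least 200 bp (1.5). Spermatogonia, Sertoli cell and blood or peritubular lists had under 3 members measured, namely Kit with -1.11 (SE 0.33), Id4 with 0.64 (SE 0.78), Clu with -0.25 (SE 0.37) and Hba-a2 with -0.69 (SE 1.41).

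Over all 4999 features, 358 were at least 2-fold higher in the supernatant and 271 lower, with a median log2 ratio of 0.02 and quartiles of -0.22 and 0.28. Many of these rest on a value of 0: 275 of the higher features were listed at 0 in the lysate and 144 of the lower ones at 0 in the supernatant. All extremes taken by the rule were of this kind. Mir669a-2 (1849.78 FPKM) and Snord45b (1369.68 FPKM) led those listed at 0 in the lysate, and Mir467b (2911.68 FPKM in the lysate), Mir467a-6 (2038.41) and Snord19 (567.04) those listed at 0 in the supernatant. Mir669a-2, Mir467b and Mir467a-6 lie in a locus of near-identical copies on chromosome 2 (10292077 to 10516880), where reads can be split between copies, so their values are uncertain. Among features above 0 in both columns, a view chosen after the values were seen, Mir148a was at 407.396 FPKM against 5984.92, a log2 ratio of -3.87 (SE 0.43), and 83 features were higher and 127 lower.

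The second comparison asked what was retained in the pellet from which the chromatoid body is purified. Nearly all features were lower than in the lysate, with a median log2 ratio of -2.20 over 3005 features, 263 higher and 2599 lower. After centring on that median, 440 features were higher and 515 lower, so 9.19% of the 2-fold differences were increases before centring and 46.1% after. Values relative to the median follow; a common scale alone would put microRNA genes at -0.51, because the pseudocount compresses low features. microRNA genes were the lowest class, with a median log2 ratio of -4.65, which is -2.46 relative to all features, and 339 of 363 were at least 2-fold below the lysate (percentile 0). piRNA clusters had -2.44, or -0.25 relative to all features, with 179 of 180 below the lysate and ranked above expression-matched random lists (percentile 100). Against lists not matched on expression the clusters ranked at the bottom (percentile 0). Features of like expression include microRNA genes, 277 of which were at or above 1000 FPKM in the lysate. The matched percentile of the clusters may therefore reflect the feature class. Small structured RNA genes had -0.40 relative to all features over 95 genes (percentile 52.1, and 0 without matching) and other named genes 0.18.

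**Figure D1:**
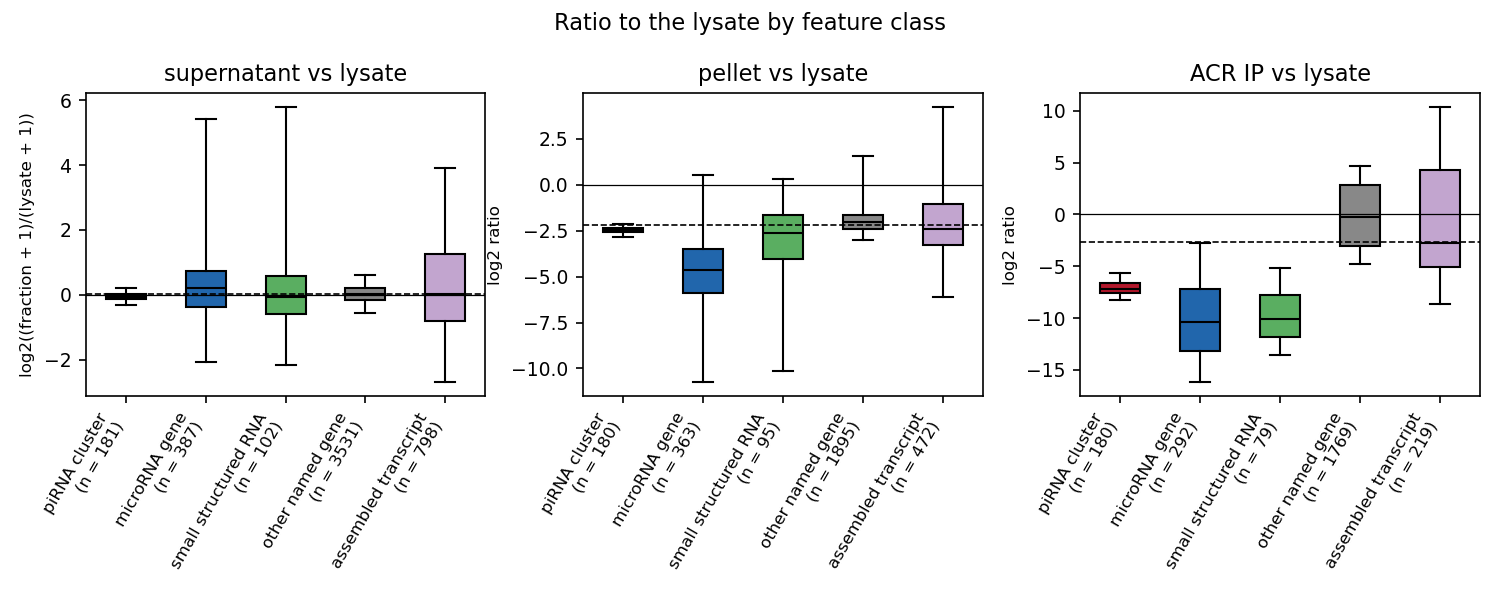
Log2 ratio of each fraction to the lysate by feature class, with boxes for quartiles, whiskers for the 5th and 95th percentiles, a dashed line for the median of all features and a solid line at 0; each panel has its own scale. In the pellet, microRNA genes have a median of -4.65 and piRNA clusters -2.44. In the ACR IP 220 of 292 microRNA genes and 42 of 180 piRNA clusters are listed at 0, so the boxes there depend on the pseudocount.

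Within the microRNA genes, the let-7 family was among the lowest in the pellet, at -3.22 relative to all features over 11 genes (percentile 0.1). Mirlet7c-2 was at 9947.27 FPKM against 601741 in the lysate, a log2 ratio of -5.92 (SE 0.15). The somatic microRNAs had -2.86 over 9 genes (percentile 1.9), with Mir202 at 4813.48 against 531875 FPKM, a log2 ratio of -6.79 (SE 0.34), and Mir451 at -5.24 (SE 0.15). The X-linked testis cluster had -2.58 over 17 genes (percentile 1.8), with Mir547 at -6.23 (SE 0.47). The miR-17-92 group had -2.40 over 14 genes (percentile 3.2), with Mir106b at -5.75 (SE 0.59). That group's percentile was 0 without matching and 0.9 for its 5 genes at loci of at least 200 bp. The Mir34 and Mir449 family was at -1.74 over 6 genes (percentile 36.3, and 0.8 without matching), with Mir34b at -3.93 (SE 0.064) and Mir449a at -3.94 (SE 0.066). All members of these lists were at least 2-fold below the lysate, but so were 2599 of all 3005 features.

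Small RNA on germ cell genes was near the middle of the pellet ratios. Chromatoid body and piRNA pathway genes had 0.01 relative to all features over 11 genes (percentile 37.3), with Mael at a log2 ratio of -2.87 (SE 1.06) and Ddx25 at -2.47 (SE 0.32). Acrosome genes had -0.22 over 5 genes (13.3), late spermatid genes -0.14 over 19 (31.7), spermatocyte genes -0.16 over 7 (31.3), nuclear long non-coding RNA 0.62 over 4 (85.5), house-keeping genes -0.07 over 7 (42.6), histone genes -0.04 over 45 (14.1) and loci without a functional name 0.09 over 302 (15.0). Ribosomal protein genes had -0.23 over 62 genes (percentile 0). The protamine genes were lower than most, with Prm1 at 26.6 FPKM against 398.008, a log2 ratio of -3.85 (SE 0.35), and Prm2 at -3.70 (SE 0.28). The Leydig cell hormone gene Insl3 had -3.71 (SE 1.22) and the Sertoli cell gene Clu -1.57 (SE 0.69).

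A small set of genes was higher in the pellet than in the lysate. In the authors' deposited table, 21 features, all of them other named genes, were called higher and 561 lower, by values not centred on their median. At a q-value below 0.05 in the authors' deposited table there were 168 and 2085. The genes called higher included the spermatogonial receptor gene Kit, at 18.2 FPKM against 5.27, a log2 ratio of 1.61 (SE 0.20), against -1.11 in the supernatant. Others among them were looked at after their values were seen: Rhbdf2 with 61.5 against 2.20 FPKM (4.29, SE 0.35), Msto1 with 151.322 against 7.66 (4.14, SE 0.27), the mitochondrial leucyl-tRNA synthetase gene Lars2 (chromosome 9, 123276057 to 123371782) with 1287.02 against 603.511, and Smc6 with 82.1 against 34.4. In the ACR IP control Smc6 was at 1154.03 against 26.6 FPKM, Msto1 at 73.4 against 4.59, Lars2 at 622.51 against 502.33 and Kit at 54.6 against 1.65, a lysate level at which nearly all genes listed in that table were higher. By the rule, the 12 highest features were all listed at 0 in the lysate, led by Snord45b (2021.28 FPKM in the pellet), AF357359 (1600.2) and an assembled transcript on chromosome 8 (73491314 to 73491842; 1178.84). The 12 lowest were all listed at 0 in the pellet, led by Mir411 (11091.4 FPKM in the lysate), Snord68 (7938.42) and Mir467b (6960.83), and included Mir376c, Mir376a, Mir134 and Mir377 from the same stretch of chromosome 12 as Mir411. Of the higher features 98 were at 0 in the lysate; among features above 0 in both columns 165 were higher and 2278 lower.

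The ACR IP with the acrosin antibody served as the control immunoprecipitation. Nearly all microRNA genes, piRNA clusters and small structured RNA genes were below the lysate in it. Of 292 microRNA genes 285 were at least 2-fold below the lysate, and 220 were listed at 0. The class median of -10.40 (percentile 0) is therefore set by the lysate values and the pseudocount; it was -13.72 with a pseudocount of 0.1. All 180 piRNA clusters were below it, with a median log2 ratio of -7.20 (percentile 83, but 0 without matching on expression and 20.8 on loci of at least 200 bp), and 42 were listed at 0. All 79 small structured RNA genes were below it, 77 of them at 0, so that their median of -10.12 (percentile 0), or -13.44 with a pseudocount of 0.1, is likewise no measured ratio. Mir34c was at 78133.2 FPKM against 8198840, a log2 ratio of -6.71. By the rule, the 12 lowest features were microRNA genes listed at 0, led by Mir425 (687800 FPKM in the lysate), Mir93 (445991), Mir10b (405376) and Mir881 (272487).

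Over all 2539 features of the ACR IP comparison, 925 were higher and 1498 lower, with a median log2 ratio of -2.70, and 1097 were higher and 849 lower after centring, which moved the share of increases from 38.2% to 56.4%. The median was 1.54 among features above 0 in both columns, so the sign for all features depends on those listed at 0. Of 1769 other named genes 822 were higher and 838 lower. Of 720 named genes listed with under 2 FPKM in the lysate 717 were higher, so the count of higher genes depends on which low genes the table lists. The acrosin control was not marked by small RNA on acrosome genes, whose median was 0.52 relative to all features over 5 genes (percentile 37.7), although Spaca3 was at 28.4 against 2.43 FPKM. Late spermatid genes had -1.06 over 16 genes (percentile 0.6), with Prm1 and Tnp1 listed at 0, ribosomal protein genes -0.46 over 41 (0.8), chromatoid body and piRNA pathway genes -0.65 over 10 (2.5), histone genes -0.73 over 12 (2.9), spermatocyte genes -0.99 over 6 (10) and loci without a functional name 0.37 over 227 (22.7). Among lists not matched on expression the late spermatid (7.4), ribosomal protein (11.7) and chromatoid body lists (21.9) lay inside the random range. Matching used the mean of both columns, so features of like mean include genes low in the lysate that are listed for a high ACR IP value. The low matched percentiles may reflect that. Among microRNA lists, the Mir34 and Mir449 family had -4.52 over 6 genes (66.7), the X-linked cluster -4.91 over 16 (34.3), the somatic list -4.91 over 9 (37.1), let-7 -8.21 over 11 (13.7) and the miR-17-92 group -8.24 over 13 (3.3). Without matching on expression these microRNA lists lay at 1.6, 0, 0.3, 0 and 0 in that order, all outside the random range. Lysate values of the numbered copies of let-7 and of most other multi-copy microRNAs were lower in this table than in the others, so their ratios are uncertain. Mirlet7b, Mirlet7d, Mirlet7e, Mirlet7g and Mirlet7i were not among those lowered. Spermatogonia, Leydig cell, Sertoli cell, peritubular, long non-coding RNA and house-keeping lists had under 3 members measured, with Insl3 listed at 0 against 28.3 FPKM, Hsd3b1 at 7.52 against 0.150, Kit at 54.6 against 1.65, Malat1 at 0.366 against 10.1, Neat1 at 0 against 5.34, Eef1a1 at 0 against 8.76 and Eef2 at 4.29 against 8.83. The 12 highest features were listed at 0 in the lysate column of this table and were 11 assembled transcripts and Mir1937b-1 (10507.7 FPKM). In the pellet table Mir1937b-1 was at 139941 FPKM in the same lysate library. The transcript on chromosome 4 (115325408 to 115326070) was at 161.995 FPKM in the supernatant table's lysate column. The ratios of both are therefore uncertain. The transcript on chromosome 1 (121104505 to 121106122) was at 0 in the pellet table's lysate column as well. In 87 higher features whose reads could be derived, the median was 4.73 ACR IP reads with a step of 20. Of these, 37 rested on at most 3 reads.

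The MVH IP is the purified chromatoid body. By FPKM, which divides by feature length, microRNA genes took all of its 20 highest positions. Read shares were not derived for this column, and in the lysate the order by reads was the opposite of that by FPKM. Mir34c was at 2472030 FPKM, 23.0% of the column, followed by Mir468 (883321), Mir34b (423339), Mir22 (397585), Mir191 (304569), Mir15b (281351), Mir375 (260361), Mir184 (255902), Mir205 (214040) and Mir449a (195906). The Mir34 and Mir449 family had a median of 195906 FPKM over 5 genes, let-7 genes 45741.5 over 11, the miR-17-92 group 32082.9 over 11, the X-linked cluster 29884.8 over 16 and somatic microRNAs 21180.9 over 8, led by Mir143 (129411). Of 195 piRNA clusters 194 were above 1 FPKM, with a median of 459.039. The highest was piRNA_cluster_177 (chromosome 17, 39983504 to 39984882) at 28330 FPKM, followed by piRNA_cluster_39 at 4307.6 and piRNA_cluster_79 at 3777.16. No mm9 annotation was at hand to look up the locus of piRNA_cluster_177, and ribosomal RNA sequence there was not excluded, so its values are uncertain as a measure of piRNA. Small structured RNA was sparse: 49 of 70 genes were listed at 0, while Snord57 was at 16192, Snord2 at 6326.76 and Snord104 at 5048.19.

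Small RNA on chromatoid body and piRNA pathway genes had a median of 1.40 FPKM over 21 genes in the MVH IP, against 0.299 for all features and 0.886 for other named genes (percentile 85.7 of unmatched lists), with Eif2c2, which encodes AGO2, highest at 56.1. Acrosome genes had 0.501 over 15 (58.0), late spermatid genes 0.0409 over 22 (32.1), spermatocyte genes 1.65 over 17 (87.2), spermatogonia genes 6.21 over 4 (89.3), house-keeping genes 1.90 over 8 (81.9), nuclear long non-coding RNA 4.84 over 3 (85.9) and loci without a functional name 0.199 over 854 (23.1). Histone genes had a median of 9.50 over 23 (percentile 100), with 4 listed at 0. Ribosomal protein genes had 2.31 over 33 (98.1), but 15 of them were listed at 0, so that median lies just above the zeros. Of 6396 other named genes 2279 were at 0. The random lists were drawn from all features, including 2081 assembled transcripts of which 1803 were at 0, so these percentiles partly reflect the feature class. Kit was at 444.061 FPKM and Meg3 at 86.6. The Leydig cell genes Cyp17a1 and Fdx1 were listed at 0, and the Sertoli cell genes Clu and Ctsl were at 7.58 and 1.77.

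Sorted round spermatids had another microRNA order. Mir184 was highest at 828641 FPKM, 17.3% of the column, followed by Mir469 (272881), Mir191 (260404), Mir16-1 (236154), Mir16-2 (216277), Mir15b (177793), Mir34c (175682) and Mir375 (149228). The Mir469 locus in this table (chromosome 5, 115300314 to 115302629) is that of piRNA_cluster_39, so its value is uncertain. The 20 highest features by FPKM were all microRNA genes. They included the X-linked Mir741, Mir871, Mir465, Mir470, Mir465b-1, Mir465b-2 and Mir465c-2, some of which are near-identical copies. The X-linked list had a median of 11003 FPKM over 17 genes, let-7 30276.2 over 11, the Mir34 and Mir449 family 41219.7 over 4, the miR-17-92 group 3311.51 over 11 and somatic microRNAs 3281.71 over 9. All 181 piRNA clusters were above 1 FPKM, with a median of 664.052 and a maximum of 5173.87 for piRNA_cluster_79. Small structured RNA genes had a median of 535.833 over 54 genes, led by Snord69 (21056.5) and Scarna17 (14165.7). Ribosomal protein genes (8.58 over 9), histone genes (3.74 over 4) and loci without a functional name (22.0 over 56) lay at percentiles of 0.2, 0.4 and 0.6 of random lists from all features. Those lists hold many microRNA genes and piRNA clusters, whereas other named genes had a median of 13.0 FPKM, so the percentiles reflect the feature class. Among the marker lists with under 3 members, Eif2c2 was at 40.3, Ddx25 at 11.5, Prm1 at 26.8, Tex101 at 13.4, Ldhc at 18.3, Meg3 at 6.64 and Kit at 25.05 FPKM.

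piRNA clusters kept nearly the same rank order through the purification. Across 180 clusters listed in every table, Spearman's rho with the lysate was 1 for supernatant, 0.99 for pellet, 0.99 for MVH IP, 0.95 for round spermatids and 0.88 for ACR IP. Clusters are not independent replicates, and these values describe single libraries. Across 77 microRNA genes under 200 bp taken as single-copy, rho with the lysate was 0.97 for supernatant, 0.84 for pellet, 0.71 for MVH IP, 0.65 for round spermatids and 0.55 for ACR IP, and that between pellet and MVH IP was 0.88. The 77 include Mir465, which has related genes such as Mir465b-1, so reads shared between copies can add to their scatter. The ACR IP values rest on few reads. With a step of 20, the median was 6.1 over 115 clusters whose reads could be derived, and at most 3 for 41 of them. In that column 42 of the 180 clusters and 30 of the 77 microRNA genes were at 0, so its rho cannot be ranked against the others. These tables were normalized separately. After centring, 177 of the 180 clusters lay within 2-fold of their lysate position in the MVH IP and 162 in round spermatids, against 44 and 24 of the 77 microRNA genes. Median implied lysate reads in the supernatant table were 9980 per cluster and 77.1 over 338 microRNA genes. How much of the wider microRNA scatter is counting noise was not tested.

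**Figure D2:**
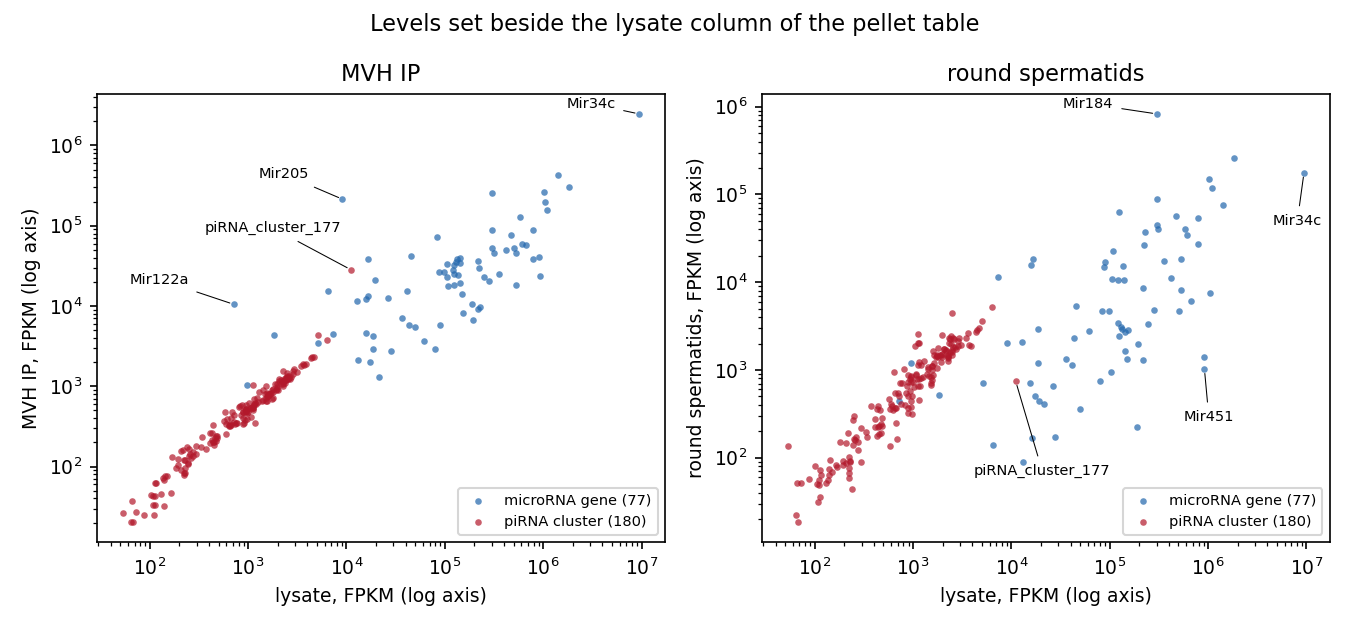
FPKM in the MVH IP (left) and in round spermatids (right) against FPKM in the lysate column of the pellet table, on log axes; points are 180 piRNA clusters and 77 microRNA genes. piRNA clusters form a narrow band from which piRNA_cluster_177 departs upward at 28330 FPKM in the MVH IP and downward at 740.318 FPKM in round spermatids.

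The balance between piRNA clusters and microRNAs lay further toward the clusters in the pellet and MVH IP than in the lysate and supernatant. The summed FPKM of the 180 clusters per 1000 summed FPKM of the 77 microRNA genes was 7.66 in the lysate, 5.29 in the supernatant, 28.4 in the pellet, 23.4 in the MVH IP and 66.8 in round spermatids. Pellet and MVH IP were thus 3.71 and 3.05 times the lysate. In the ACR IP the value was 13.3, of which piRNA_cluster_177 made up 76.4% of the cluster sum. Without that cluster, whose annotation is uncertain, an alternative chosen after seeing the data, the values were 7.28 in the lysate, 21.9 in the pellet, 18.7 in the MVH IP and 3.14 in the ACR IP, so the ACR IP lay above the lysate with the cluster and below it without. Without Mir34c the pellet was 4.27 times and the MVH IP 3.51 times the lysate.

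**Figure D3:**
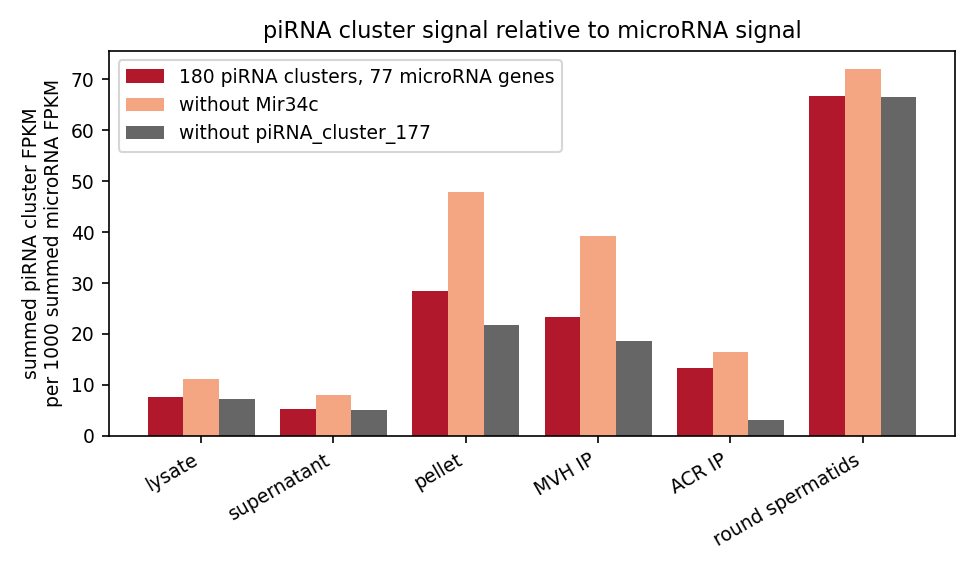
Summed FPKM of 180 piRNA clusters per 1000 summed FPKM of 77 microRNA genes in 6 columns (bars), and the same without Mir34c or without piRNA_cluster_177. Pellet (28.4) and MVH IP (23.4) stand above lysate (7.66) and supernatant (5.29) in each version, while the ACR IP goes from 13.3 to 3.14 without piRNA_cluster_177.

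The ratios to the lysate were also compared between fractions, across features. Spearman's rho was 0.11 between supernatant and pellet over 2810 features, -0.02 between supernatant and ACR IP over 1797, and 0.63 between pellet and ACR IP over 1760. All ratios share the lysate library. Simulated fractions that differed from it only by a common scale and counting noise gave a mean rho of 0.36, 0.13 and 0.78 over 2674, 1764 and 1690 features, on which the observed rho was 0.02, -0.04 and 0.61. On the same features, the observed covariance was 0.06 for supernatant and pellet against 0.45 simulated, -0.09 for supernatant and ACR IP against 0.33, and 4.71 for pellet and ACR IP against 1.68. By class, the pellet and ACR IP ratios had a rho of 0.60 over 1069 other named genes, 0.08 over 292 microRNA genes and 0.06 over 180 piRNA clusters. The lysate could not be split, and part of any agreement may come from sharing it. With few exceptions, features are listed from about 2.88 FPKM in the higher column of the pellet comparison and 4.53 in that of the ACR IP. Genes low in the lysate are thus listed in both mainly when high in both fractions, which by itself raises rho. The ACR IP was also made from the second pellet, so its agreement with the pellet can follow from the design.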

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

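All tests in this part were chosen after the results were seen. Medians of 4 gene lists lay on opposite sides of all features in the supernatant and in the pellet, each outside the central 95% of matched random lists; with 1 library per fraction the difference was not tested. All microRNA genes had a centred median log2 ratio of 0.19 in the supernatant and -2.46 in the pellet. The let-7 family had 0.47 and -3.22, the X-linked testis microRNA cluster 0.41 and -2.58, and ribosomal protein genes 0.16 and -0.23.

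The low position of microRNAs in the pellet was weighed against technical explanations. A common difference in scale between the columns, with the pseudocount, would give microRNA genes a centred median of -0.51. The 353 microRNA genes above 0 in the lysate lay below what that scale gives (median log2 difference -1.98, 95% bootstrap interval -2.16 to -1.79), while piRNA clusters were at 0.24. The bootstrap here and below resampled genes as if independent, so its intervals give the spread over genes and not between libraries. Few reads and the pseudocount would spare abundant genes, and the 277 microRNA genes at or above 1000 FPKM in the lysate had a difference of -1.95 (interval -2.08 to -1.77). Short genes alone would lower small structured RNA genes as much: with reference transcripts under 200 nt, the median of 333 microRNA genes minus that of 87 small structured RNA genes was -2.09 (95% bootstrap interval -2.58 to -1.58 over 10000 draws). By locus length the difference was -1.35 (-3.60 to -0.41), with only 12 structured RNA genes under 200 bp, and smaller effects of length stay open. A candidate explanation from the design is that microRNAs stay in the soluble fraction; the supernatant median of 0.19, with 238 of 387 microRNA genes above the middle of all features, is in line with that but small, and a difference between library preparations was not tested.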

How the results depend on the processing

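No paired analysis was possible because the groups compared have 1 library each. The MVH IP libraries share 1 column, so leaving out each replicate was not run. Counts at few reads are limited by depth, most of all in the ACR IP. The alternative of features above 0 in both columns, and those without Mir34c or piRNA_cluster_177, were chosen after seeing the data. Of the recomputed values of the comparisons, 62 stayed within 1.5 times the main count or within 0.1 of the main log2 value or rho, 35 moved by more and 1 changed sign, as follows. Fewer features enter at higher thresholds and filters; otherwise the cause was not tested. Features higher and lower in the supernatant (358 and 271 in the main setting) were 120 and 107 with a pseudocount of 10, 126 and 124 at or above 10 FPKM, 181 and 97 at 4-fold, and 83 and 127 above 0 in both columns. In the pellet (263 and 2599) they were 94 and 1175 with a pseudocount of 10, 122 and 1400 at or above 10 FPKM and 440 and 515 after centring; 157 were higher at 4-fold and 165 above 0 in both columns. In the ACR IP (925 and 1498) they were 414 and 987 with a pseudocount of 10; 460 were higher at or above 10 FPKM, 849 lower after centring and 452 lower above 0 in both columns. The pellet median (-2.20) was -2.70 with a pseudocount of 0.1, -0.75 with 10, -2.56 at or above 10 FPKM and -2.10 without microRNA and small structured RNA genes. The ACR IP median (-2.70) was -4.40, -0.70, -4.06 and -1.63 in these settings, -2.52 on loci of at least 200 bp, and turned to 1.54 above 0 in both columns, since 1046 of the lower features are listed at 0 in the ACR IP. In the MVH IP 3776 features were at or above 1 FPKM and 1374 at or above 10 FPKM. Between fractions, Pearson's r was 0.38 for supernatant and pellet and 0.08 for supernatant and ACR IP, and rho for pellet and ACR IP was 0.48 at or above 10 FPKM and 0.38 with a pseudocount of 0.1. Of the recomputed list medians 113 moved by under 0.1 and 25 by more. The largest moves were in the ACR IP with a pseudocount of 0.1, where many members of these lists are listed at 0: all microRNA genes from -10.40 to -13.72, small structured RNA from -10.12 to -13.44, let-7 from -10.90 to -14.23, the miR-17-92 group from -10.94 to -14.26, chromatoid body genes from -3.35 to -6.54, late spermatid genes from -3.75 to -6.65, spermatocyte genes from -3.69 to -6.91, histone genes from -3.43 to -6.62 and ribosomal protein genes from -3.16 to -6.29. Without matching on expression, all lists outside the random range in the supernatant and pellet stayed outside it, and 2 of 5 did in the ACR IP; the pellet piRNA clusters did so by turning from percentile 100 to 0. A further 2 lists in the supernatant, 3 in the pellet and 6 in the ACR IP moved outside it, so list positions depend on matching most of all in the ACR IP. On loci of at least 200 bp, 1 list in the supernatant and 1 in the pellet moved outside the random range. With a pseudocount of 0.1, 1 list in the ACR IP did.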

Other observations

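All tests in this part were chosen after the results were seen. Of the 16 microRNA genes at least 2-fold higher in the pellet, 3 known from other tissues were looked at after their values were seen. No test of a tissue origin was made, and all 9 measured genes of the list of microRNAs from other cell types were lower in the pellet. The muscle microRNA Mir1-1 was at 21191.9 FPKM in the pellet against 2953.28 in the lysate (log2 ratio 2.84, SE 0.49), and the epithelial microRNA Mir205 at 30155 against 9098.96 (1.73, SE 0.36). The liver microRNA Mir122a was at 1726.64 against 714.616 in the pellet (1.27, within its SE of 1.39). In the ACR IP Mir122a was at 3112.6 against 622.52 and Mir205 at 8492.51 against 7926.34. With 1 ACR IP read worth 10 or 20 lysate reads, these ACR IP values can rest on few reads. Of 292 microRNA genes in the ACR IP, 4 were above the lysate, Mir122a and Mir205 among them. Whether the control was depleted of Mir1-1, Mir205 or Mir122a was left open, and a high position in the MVH IP cannot be called particular to MVH. In the supernatant Mir205 was below the lysate, at 997.592 against 3806.58 FPKM (-1.93, SE 0.54). In the MVH IP Mir205 ranked 9 of all features and Mir1-1 ranked 15, and Mir205 was the microRNA gene of the 77 compared farthest above its lysate position, by 7.07 log2 units after centring. Mir122a was at 6.39, which is uncertain because its lysate value is low for a microRNA gene and its SE large.

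In round spermatids, set beside the lysate, Mir184 (5.91), Mir92b (5.12) and Mir760 (4.76) stood farthest above the middle of the 77 microRNA genes in log2 units, and the red cell microRNA Mir451 (-5.37), Mir19a (-5.27) and Mir99a (-4.88) farthest below it. These tables were normalized separately. piRNA_cluster_177 was the cluster farthest above its lysate position in the MVH IP (2.35) and farthest below it in round spermatids (-3.29), and it was the only cluster not below the lysate in the pellet (11581.2 against 11079.9 FPKM). Whether its locus holds ribosomal RNA sequence could not be looked up, so these values are uncertain as a measure of piRNA. Among piRNA clusters in round spermatids, piRNA_cluster_158 (1.96) and piRNA_cluster_49 (1.79) on chromosomes 14 and 6 were highest relative to the lysate.

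In the ACR IP table the lysate column was below 0.5 times its usual ratio to the pellet table's lysate for 42 of 291 microRNA genes. Low read numbers would lower rare genes, but the median of these 42 was 113308 FPKM against 12377.5 for the others, 9.2 times as high. Reads shared between near-identical copies may account for it: 36 of the 42 (85.7%) carry a copy number in their name, such as Mir16-1 and Mirlet7c-2, against 6 of 249 (2.4%). That would mean that the ACR IP table alone handled reads with several matches in another way, which the sources used here do not state.

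Named genes higher in the pellet formed a set of 145 above 0 in both columns. Of all 1828 named genes above 0 in both columns, 114 exceeded 0 by more than 3 times the implied SE, and 102 of these were in the set. A normal error would give 2.47 if genes were listed whatever their pellet value. However, the set's median lysate value was 1.055 FPKM, against 7.22 for the other genes. In the pellet comparison features are listed from about 2.88 FPKM in the higher column. Set genes below that level in the lysate are thus listed only through their pellet value. Counting error was therefore not excluded for the set as a whole. The set was also looked at in the ACR IP control. Of 9 set members at or above 5 FPKM in that table's lysate 7 (77.8%, exact 95% interval 40 to 97.2) were at least 2-fold above it, against 20 of 880 other genes (2.3%, or 2.22% at the set's lysate levels). Both ratios share the lysate library, so 3 SE of the pellet ratio, which include the lysate's counting error, were taken off each set gene, and the count stayed at 7. Both IPs were made from the second pellet, so genes high in the pellet can carry over into either of them. The comparison with the lysate therefore cannot tell whether MVH enriches the set, and no conclusion on that is drawn. For the rest of the set the ACR IP ratios are not informative, because nearly all low genes that the table lists are above the lysate. The 7 included Smc6 (1154.03 against 26.6 FPKM) and Cacna1d (321.84 against 5.07). In the MVH IP the set's median was 54.1 FPKM over 96 genes against 3.58 over 1293 other genes. Reads from simple repeats are a possible explanation for part of the set: of 129 genes with a GENCODE M21 transcript, 57 (44.2%) held a perfect run of at least 18 nt of a unit of 1 to 3 nt, against 23.8% of 1482 other genes and 29.1% expected from other genes of the same transcript length. Of 15 units the relative excess was largest for ATC (7.8% against 0.3%), a unit singled out after the values were seen, and absent for A (8.5% against 9.4%). The remaining genes of the set are left without an explanation.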
